A study of Caenorhabditis elegans with 2 samples.

How the data were processed

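Chromatin immunoprecipitation with sequencing (ChIP-seq) recovers the DNA bound by a protein and counts it along the genome. Here the protein was NHR-77, a nuclear hormone receptor of the nematode Caenorhabditis elegans, carried as a green fluorescent protein (eGFP) fusion by a transgenic strain with an unc-119 mutant background. Both samples came from whole fourth-stage (L4) larvae of mixed sex, and the labels call them biological replicates 1 and 2. They form 1 group. No untagged or untreated sample was analysed here, so no comparison between groups was made.

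For each replicate the authors deposited a list of 30000 regions that holds peaks and background together, and the same kind of list for both replicates pooled. From these 3 lists the authors derived, per the deposited file listings, a set of peaks. These passed a threshold on the irreproducible discovery rate (IDR), which rests on how alike regions rank in both replicates. All lists exist for the builds ce11 and ce10. Per the deposited file listings, both replicates were called against the same control. The strain and type of this control, the aligner, the peak caller, their versions, the IDR threshold, the treatment of reads that map to several places and the read depth are not given in the sources used here. The depth is therefore unknown, and the intervals below cover counting of peaks or genes only. The signal value of a region is the authors' own enrichment value as deposited, and its scale differs between lists, so it was used to rank regions within a list. The deposited −log10 q of each region is also the authors' own. The position of the summit within a region was taken from the deposited offset. A region counts as a peak here only if it is in the IDR-thresholded set. That set held all regions of the pooled list with a signal at or above its lowest value, 3457 of 3457 in ce11. It thus equals a cut on pooled signal, and single peaks can rank unlike in the replicates. The peak near vha-12, for example, ranked 4775 in replicate 1 and 106 in replicate 2.

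Positions were compared with the WBcel235 assembly (ce11) and Ensembl annotation release 115. No coordinates were converted, and ce10 lists were used only for results that need no annotation. Coordinates are printed counting from 1. An annotated start is the 5′ end of any annotated protein-coding transcript. Many worm transcripts are trans-spliced, so an annotated start often lies downstream of the true start of transcription. Each summit was placed in 1 class by priority: within 500 bp of a protein-coding start, exon, intron, intergenic. Class counts were compared with 100000 random placements within the same chromosomes, with each summit drawn independently and every base equally likely. Chromosome shares were compared with shares of length by exact binomial tests. A gene counted as near a peak if a summit lay within 500 bp of any of its starts. Each of 31 gene lists fixed before the data were examined was compared with all other protein-coding genes by a two-sided Fisher's exact test. The pattern for chemoreceptors also takes src-1, a kinase gene. Odds ratios and their 95% intervals carry 0.5 added to each cell. Gene classes with at least 20 genes were tested in the same way with the gene's own start, against all other annotated genes. Each of 20 fixed motifs and all 2080 words of 6 bases (a word and its reverse complement counted as 1) were searched within 50 bp of each summit and within 50 bp of a point 300 bp away on a random side. The paired presence was compared by a two-sided exact McNemar test, and by Fisher's exact test where regions below the threshold were the control. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05. Shares carry 95% Wilson intervals. Correlations across peaks carry two-sided permutation p-values from 100000 pairings, and peaks are not independent replicates. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.

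The genes named are, by a rule fixed before the data were examined, the gene with the start nearest to each of the 20 strongest peaks, the 3 members with the strongest nearby peak for each list past the threshold and 1 member for the other lists, together with nhr-77 and unc-119. The name of a nearest gene states proximity only. Starts inside a gene count too. The summits counted for fat-4, cox-6B, zip-2, egl-27, daf-3, act-4 and nlp-40, for example, lay in introns of the gene itself. Others lay in a neighbouring gene, such as that for pbs-3 in ulp-2 and that for fbxc-19 in fbxa-3.

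The code was tested on simulated data. In 20 random gene sets of the observed size, tested against the 31 lists, 0 lists passed the threshold. With summits placed uniformly, 2 list calls arose over as many sets of placements. Of 80 genes given a planted summit, 80 were recovered. A word planted in 20% of random windows ranked 1 among all words, and 0 motifs and 0 words passed before it was planted.

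Alternatives fixed before the data were examined were the 1728 strongest peaks, the ce10 lists, other overlap rules, other windows, other controls and backgrounds, and each replicate alone (the strongest regions of 1 replicate, as many as there are peaks). The tests of chromosome X by rank, of the 12-base motif and of words by gene list were added after the data were seen.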

Results

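Sites recovered by ChIP-seq of eGFP-tagged NHR-77 were mapped in whole L4 larvae in 2 biological replicates. Since no untagged sample was analysed here, binding by NHR-77 itself cannot be told from other recovery. The replicate lists and the pooled list held 30000 regions each, background included. Signal values ran from 5.11 to 233 in replicate 1, from 5.39 to 385 in replicate 2 and from 9.01 to 596 in the pooled list. A q-value under 0.05 was attached to 9386 regions of replicate 1, 11287 of replicate 2 and 8873 of the pooled list. The IDR-thresholded set held 3457 peaks in ce11, which covered 1.17% of the genome and had pooled signal values of 46.7 to 596 with a median of 67.1.

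The first question was how alike the replicates were. The strongest sites were shared almost completely. Of the 100 strongest regions of replicate 1, 99 overlapped one of the 3457 strongest of replicate 2, and 100 of 100 did so in the other direction. The peak upstream of rpl-3, which encodes a protein of the large ribosomal subunit, ranked 2 in replicate 1 and 1 in replicate 2. The peak near cdc-48.1, a segregase ATPase, ranked 10 and 2. Sharing with these 3457 fell with rank, to 43.3% and 43.7% for regions ranked after 2000. Of the same regions, 92.3% and 92.8% overlapped some region of the whole list of the other replicate. Part of the fall comes by construction, since regions near the cut can land on either side of it. Over all 3457 strongest regions, 63.3% of those of replicate 1 (Wilson interval 61.6 to 64.9) and 63.6% of those of replicate 2 (61.9 to 65.1) overlapped, against 2.28% and 2.24% on average for randomly placed regions. The shares were 61.6% and 61.8% for the 1728 strongest of each, and 61.9% and 63.0% for the 6914 strongest.

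Of the 3457 thresholded peaks, 3405 (98.5%) overlapped a region in both replicate lists. Across these peaks, which are not independent replicates, the log2 signals correlated with Spearman's rho 0.41 and Pearson's r 0.51 (permutation p = 1e-05 for both, the smallest possible, adjusted value 1e-05 over these 2). Pearson's r was 0.51 without the 2 peaks farthest from the median of replicate 1. The peaks were selected on their pooled signal, which narrows the range over which the replicates could correlate.

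**Figure D1:**
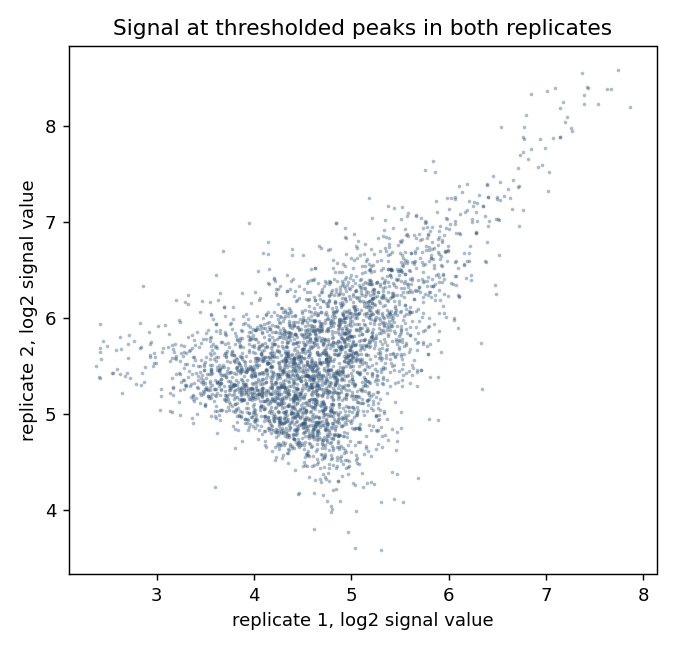
Signal value (log2, no common scale between lists) of replicate 1 on the horizontal axis and of replicate 2 on the vertical axis, 1 point for each of the 3405 peaks with a region in both lists. Spearman's rho is 0.41 over these peaks, and 0.40 over the 1715 of the 1728 strongest peaks that have a region in both lists.

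The second question was where the summits lay. Summits gathered at the 5′ ends of protein-coding genes. Within 500 bp of an annotated start lay 1765 of 3457 summits, 51.1% (Wilson interval 49.4 to 52.7), against 22.9% under random placement, a 2.23-fold excess (one-sided permutation p = 1e-05, the smallest possible). Exons held 8.39% against 23.8% and introns 13.3% against 27.1% (adjusted permutation p = 2.67e-05 for each, two-sided, the smallest the placements allow). The median summit lay at -179 bp from the nearest start, where negative distances are upstream, and 72.7% of summits were upstream. A distance over 2000 bp from any such start was found for 18.5%. The intergenic share, 27.2% against 26.2%, did not pass (adjusted permutation p = 0.174). It was 36.9% with a start window of 250 bp, then above random, and 19.8% with 1000 bp, then below random.

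**Figure D2:**
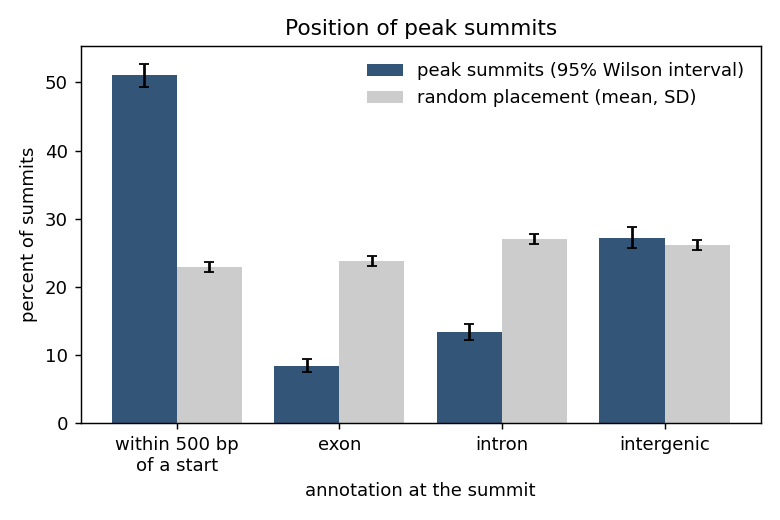
Percent of the 3457 summits in each annotation class (blue, 95% Wilson interval) and the mean of 100000 random placements (grey, SD). Starts held 51.1% of summits against 22.9% at random, and exons 8.39% against 23.8%.

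Peaks were denser on chromosome X and in the middle of the autosomes. Chromosome X carried 702 peaks, 20.3% (Wilson interval 19 to 21.7) against 17.7% of the length (exact binomial test, adjusted exact p = 0.000196). Chromosome II was also above its length share, at 16.9% against 15.2% (adjusted exact p = 0.00974). Chromosomes IV (15.6% against 17.4%, adjusted exact p = 0.00598) and V (18.6% against 20.9%, adjusted exact p = 0.00246) were below theirs, that of V not with the 1728 strongest peaks (19.1%, adjusted exact p = 0.106). Chromosomes I (483 peaks) and III (505 peaks) did not pass, except without replicate 1 (I at 13.7%, adjusted exact p = 0.0341, and III at 15.2%, adjusted exact p = 0.0228). The middle 33.3% of the length of the autosomes held 43.3% of their peaks (adjusted exact p = 1.4e-26). The middle of X, taken in the same way, held 34.6% of the peaks of X (adjusted exact p = 0.471). Length was the only expectation here, so any uneven density of genes or starts was not taken into account.

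The strongest peaks differed from the rest in position. Of the 20 strongest, 13 lay on X (65%, Wilson interval 43.3 to 81.9), whereas 689 of the remaining 3437 peaks did (two-sided Fisher's exact test, adjusted p = 5.06e-05 over 3 sizes of the top set, a test chosen after the ranking was seen). For the 50 strongest, the share was 42% (adjusted exact p = 0.000764), and for the 100 strongest it was 27% (adjusted exact p = 0.101). None of the 13 peaks on X, 0 of 13, lay within 500 bp of a protein-coding start, and their median distance was 2578 bp. All 7 autosomal peaks of the top 20 lay within 500 bp of one, at a median distance of 158 bp.

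Rank 1 was the intergenic peak at chromosome III, 3867427 to 3867731, with its summit at -266 bp from rpl-3 and a signal of 596. The other autosomal peaks of the top 20 lay at cdc-48.1 (signal 540), R09E12.9 (519), Y17G9B.5 (496, between this gene and rpl-20), rpl-15 (461), tasp-1 (441) and the cytochrome P450 gene cyp-34A9 (398). On X, the strongest was the intergenic peak from 11093891 to 11094437, ranked 3 with a signal of 539 and ranked 3 and 7 in the replicates. Its nearest start was that of W02H3.3, 4001 bp away. Others were intergenic at 9465654 to 9466039 (ZK899.6, signal 531), 11937276 to 11937770 (F55G7.5, 519), 12362878 to 12363408 (F19H6.5, 504) and 806486 to 806849 (gtr-1, 469). Further intergenic peaks were nearest to F22H10.2 (16681883 to 16682339, signal 468), nspc-17 (14525395 to 14526194, 443), F20B6.9 (4209039 to 4209493, 417), K02D3.1 (13700644 to 13701044, 408) and the F-box gene fbxb-58 (1626927 to 1627390, 387). A peak from 8036184 to 8036684 (signal 429) lay in intergenic DNA at -4874 bp from xol-1, the switch gene of sex determination. The peak at 6296343 to 6296876 (signal 484) was in an intron of mom-1 and had cest-16 as its nearest start. The peak at 5429357 to 5429754 (signal 416) was in a coding exon of pks-1, a polyketide synthase gene, with C41A3.2 as its nearest start.

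**Figure D3:**
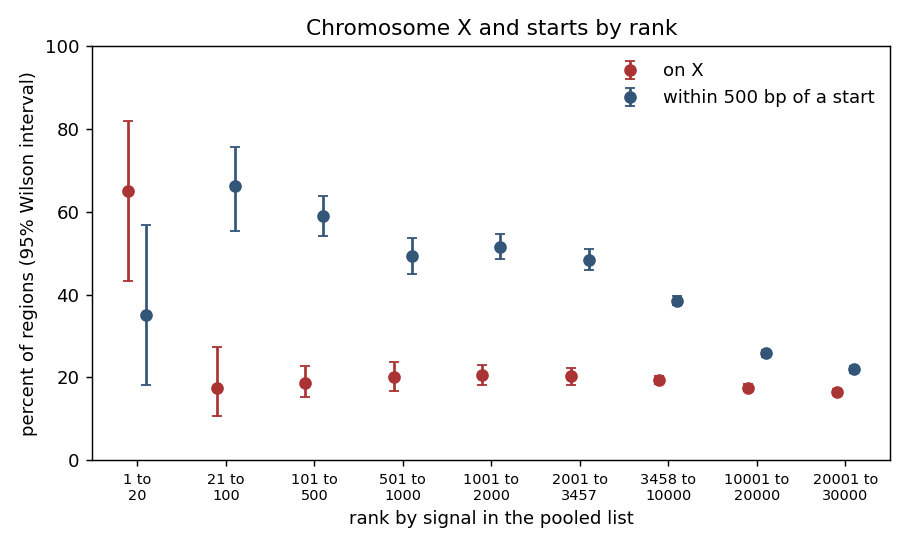
Percent of regions on X (red) and within 500 bp of a protein-coding start (blue), with 95% Wilson intervals, by rank of signal in the pooled list. The share on X was 65% in the top 20 and between 16.5% and 20.5% in the later classes, and the share near starts was 66.3% for the next 80 regions and 21.9% for the last 10000.

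The third comparison asked which genes had a peak at their start. In all, 2047 of 19973 protein-coding genes (10.2%) had one, and 14 of 31 fixed lists were near peaks more often than other genes, 7 less often, while 10 did not pass. With the window of 500 bp, ribosomal proteins had the highest odds of the lists. Of 80 ribosomal protein genes, 61 had a peak (76.3%, log2 odds ratio 4.83, 95% interval 4.09 to 5.57, adjusted exact p = 5.02e-43), led by rpl-3, rpl-20 and rpl-15. With a window of 250 bp they were 18 of 80 (22.5%, log2 odds ratio 2.02, adjusted exact p = 3.64e-05), below 7 other lists, and with only the nearest gene counted 38 of 80 (3.31), below the V-ATPase (3.43). Translation factors had 18 of 42 (log2 odds ratio 2.74, adjusted exact p = 2.83e-07), led by iff-2 (rank 21), eef-1A.1 (rank 77) and eef-1G (rank 79). Splicing genes had 19 of 55 (2.24, adjusted exact p = 3.89e-06), with rsp-2, snr-4 and snr-2 at ranks 271, 337 and 697.

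The lists of the V-ATPase, the respiratory chain, chaperones and the proteasome were also near peaks more often than other genes. Subunits of the V-ATPase, the vacuolar proton pump, had 12 of 20 (log2 odds ratio 3.69, adjusted exact p = 3.86e-07), led by vha-1, vha-12 and vha-8. This fell to 8 of 20 without replicate 2 (2.64) and to 5 of 20 with a window of 250 bp (2.28), past the threshold in both. The respiratory chain had 21 of 47 (2.84, adjusted exact p = 1.37e-08), and its leading members cox-6B, cox-5A and cox-5B, all of cytochrome c oxidase, had peaks ranked 53, 54 and 55. Chaperones had 25 of 65 (2.48, adjusted exact p = 1.37e-08), led by hsp-1, hsp-110 and cct-1, and were at 1.37 with a window of 250 bp and 1.47 with only the nearest gene counted. The proteasome had 11 of 33 (2.17, adjusted exact p = 0.000693), led by rpn-3, pbs-2 and pbs-3. The peak of rank 61, at chromosome III, 8447051 to 8447277, lies between hsp-110 and rpn-3 and was counted for both.

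Intestinal and detoxification genes formed another group. The intestine list had 25 of 80 (log2 odds ratio 2.02, adjusted exact p = 9.47e-07), led by spp-5, cpr-4 and elt-2, the last a GATA factor of intestinal fate with its peak at -423 bp. Glucuronosyltransferases had 20 of 67 (1.93, adjusted exact p = 2.28e-05), led by ugt-20, ugt-26 and ugt-25, and were at 1.32 without replicate 2. Lipid metabolism had 32 of 127 (1.59, adjusted exact p = 3.89e-06), led by fat-4, a fatty acid desaturase, cpt-2 and acs-7. Cytochromes P450 had 16 of 74 (1.31, adjusted exact p = 0.00536), led by cyp-34A9, cyp-29A2 and cyp-33C7. Glutathione transferases had 10 of 47 (1.30, adjusted exact p = 0.037), led by gst-27, gst-42 and gst-20. The summit counted for gst-27 lay in exons of a noncoding RNA gene and a small nucleolar RNA gene. Among regulators, the receptors' own family had 49 of 274 (0.96, adjusted exact p = 0.000298), led by nhr-178, nhr-238 and nhr-135, and other transcription factors had 29 of 150 (1.10, adjusted exact p = 0.00188), led by zip-2, ztf-7 and egl-27.

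Chemoreceptor, neuropeptide, homeobox, epidermal, sperm and F-box lists were near peaks less often. Chemoreceptors had 16 of 1365 (1.17%, log2 odds ratio -3.33, adjusted exact p = 3.61e-43), with srz-62, srlf-7 and srh-70 the strongest. Neuropeptides had 1 of 140 (nlp-40, log2 odds ratio -3.42, adjusted exact p = 2.28e-05), and homeobox genes 1 of 96 (ceh-38, -2.87, adjusted exact p = 0.00131). With so few members near peaks these values moved, for neuropeptides to -4.99 without replicate 1, -2.61 without replicate 2 and -1.67 with a window of 1000 bp, and for homeobox genes to -1.55 without replicate 2. Of the hypodermis list, 2 of 105 had a peak (grl-26 and ptr-21, -2.25, adjusted exact p = 0.00313). The summit counted for grl-26 lay in its intron and also in exons of a transfer RNA gene and a noncoding RNA gene. Cuticle collagens had 6 of 175 (-1.58, adjusted exact p = 0.00277), led by col-38, col-85 and bli-6. Sperm genes had 5 of 143 (-1.53, adjusted exact p = 0.00788), led by nspa-9, spe-48 and spe-39. The F-box and MATH-BTB families had 23 of 412 (-0.94, adjusted exact p = 0.00188), led by fbxb-72, fbxa-108 and fbxc-19.

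The lists that did not pass were histones (4 of 81, his-37 strongest), the cytoskeleton (6 of 32, tba-2), germline (3 of 66, puf-9), C-type lectins (18 of 240, clec-72), signalling pathways (5 of 36, daf-3), pan-neuronal genes (1 of 26, unc-11), insulin signalling (1 of 22, daf-16), dosage compensation and sex (2 of 19, sdc-2), muscle (3 of 33, act-4) and vitellogenins (0 of 6). Against the 7554 genes with any pooled region near a start, 9 lists remained higher. Nuclear hormone receptors, cytochromes P450, glutathione transferases, lipid metabolism and the proteasome then lost their call, as did sperm and the F-box families among the lower ones. Of those that kept it, log2 odds ratios moved most towards 0 for chemoreceptors, to -1.02, translation factors, to 1.52, and splicing, to 1.29. Glutathione transferases also lost it without replicate 1 (log2 odds ratio 1.14), and the F-box families without replicate 2 (-0.41), while the cytoskeleton passed without replicate 1 (1.63) and histones without replicate 2 (-1.80). With a window of 250 bp, the calls of other transcription factors, the hypodermis list and the F-box families were lost, with 1000 bp that of glutathione transferases, and with the 1728 strongest peaks that of homeobox genes.

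**Figure D4:**
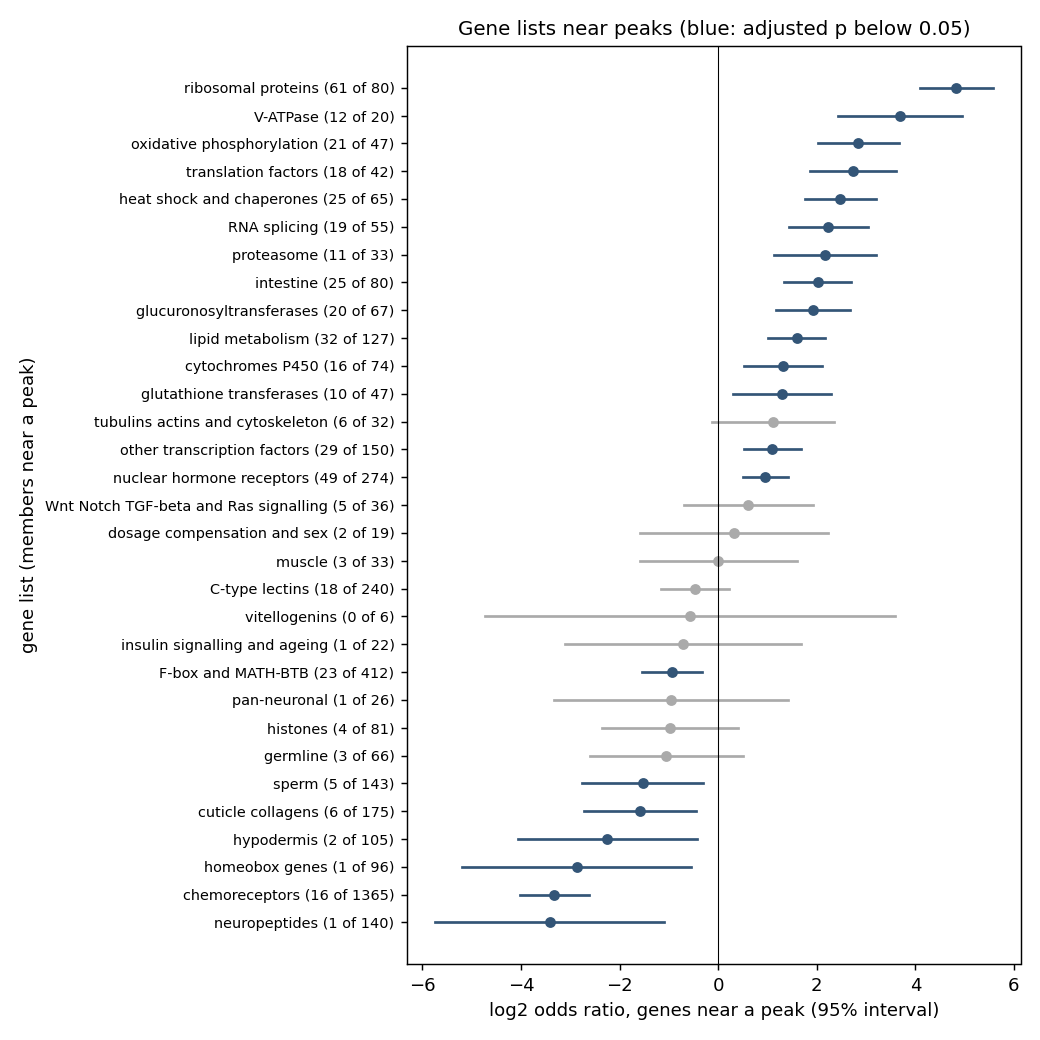
Log2 odds ratio (95% interval) of being near a peak for each of the 31 gene lists against all other protein-coding genes, blue where the adjusted p is below 0.05. Ribosomal proteins (61 of 80) are at the top, and neuropeptides (1 of 140) and chemoreceptors (16 of 1365) at the bottom.

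Small RNA genes were compared in the same way. Transfer RNA genes were near a peak in 144 of 612 cases (23.5%, log2 odds ratio 2.19, adjusted exact p = 1.48e-41, and 1.55 with the 1728 strongest peaks) and small nucleolar RNA genes in 75 of 346 (21.7%, 2.02, adjusted exact p = 5.72e-20). Long intergenic RNA genes (22 of 194, 0.90, adjusted exact p = 0.0193) and other noncoding RNA genes (0.41, adjusted exact p = 6.24e-09) were also higher, the first not with a window of 250 bp (0.69). The comparison was all other annotated genes, and the 15363 piRNA genes lower its share. Other noncoding RNA genes, at 8.10%, lay above that share (6.24%) but below the protein-coding genes (9.60% by the gene's own start). An excess over genes other than piRNA genes was not tested. Neither the microRNA genes (24 of 261, 0.56, adjusted exact p = 0.123) nor the small nuclear RNA genes (14 genes or 10.9%, 0.84, adjusted exact p = 0.097) passed. The microRNA genes passed without replicate 1 (0.72), without replicate 2 (0.83) and with a window of 1000 bp (0.73), but turned to -0.30 with 250 bp (9 of 261). The small nuclear RNA genes passed with the 1728 strongest peaks (1.32), without replicate 1 (0.98) and with windows of 250 bp (1.21) and 1000 bp (0.86), but not without replicate 2 (0.41). The piRNA genes, at 1.31% (-2.91, adjusted exact p = 7.8e-285), and pseudogenes, at 1.79% (-1.98, adjusted exact p = 1.86e-25), were lower. Copies of tRNA genes are near-identical, and how their reads were placed is not given in the sources used here.

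The fourth question was which sequences lay at the summits. Against the flanks, GA repeats and the extended GATA site had the highest ratios of the fixed motifs found there. The GATA motif WGATAR was within 50 bp of 40.2% of summits against 20.8% of flanks (exact McNemar test, adjusted exact p = 3.66e-65), and its extended intestinal form, CTGATAAR, of 7.41% against 1.13% (6.56-fold, adjusted exact p = 5.7e-40). The repeat GAGAGAGA was at 4.95% against 0.636% (7.77-fold, adjusted exact p = 2.41e-29). The E-box CACGTG was at 5.55% against 1.85% (3.00-fold, adjusted exact p = 4.27e-16), and the GC box CCGCCC at 4.05% against 1.33% (3.04-fold, adjusted exact p = 2.02e-12). Against regions below the threshold, the ratios were lower for GAGAGAGA (3.03), CTGATAAR (2.85) and CCGCCC (1.98), and CACGTG, at 2.93, then lay above CTGATAAR. The smallest adjusted p in that comparison was that of the T block TTTTTTTT, which was lower at summits (ratio 0.329, adjusted exact p = 2.91e-92, and 0.527 against flanks). In a window of 51 bp, CTGATAAR was at 12.3-fold. The half-site AGGTCA, the core of many nuclear receptor sites, was at 3.15% against 2.23% (1.42-fold, adjusted exact p = 0.0242). This call was lost in 6 of 7 alternatives, including both single replicates, with adjusted p up to 0.243 and ratios from 1.21 to 1.41. The wider summit window kept it, with a ratio of 1.42 (adjusted exact p = 0.00126). The half-site of the DAF-12 type, AGTTCA, was lower at summits (5.35% against 7.23%, ratio 0.740, adjusted exact p = 0.00179), in 6 of 7 alternatives past the threshold and not in a window of 51 bp (0.802). The variant AAGTCA did not pass (ratio 1.20, adjusted exact p = 0.121). The extended site TCAAGGTCA was at 2 summits (adjusted exact p = 0.5).

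In all, 10 motifs were higher at summits, 7 lower and 3 not past the threshold. The splice acceptor (3.85% against 10.4%, adjusted exact p = 5.99e-27, ratio 0.368, and 0.232 with the 1728 strongest peaks) and the homeobox core TAATTA (2.11% against 5.35%, adjusted exact p = 3.53e-12) were among the lower ones. Of 2080 words of 6 bases, 667 were higher and 464 lower. The leading words were CTTATC (690 of 3457 summits, against 3.91% of flanks, adjusted exact p = 3.52e-95), TGATAA (28.9% against 9.98%, adjusted exact p = 2.99e-84) and GAGAGA (21% against 5.87%, adjusted exact p = 2e-75). The word ACGCAG was at 11.9% against 2.0% (adjusted exact p = 3.42e-61). Summit windows had 41.9% G or C and flanks 35.1%. Among words with as many G or C bases, CTTATC ranked 1 of 492 by its ratio, TGATAA 1 of 192, ACGCAG 1 of 492 and GAGAGA 3 of 640. CACGTG ranked 27 of 492 and AGGTCA 170 of 640. The median ratio was 0.699 for words with 1 G or C base and 1.38 for words with 4, so ratios partly follow base composition.

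**Figure D5:**
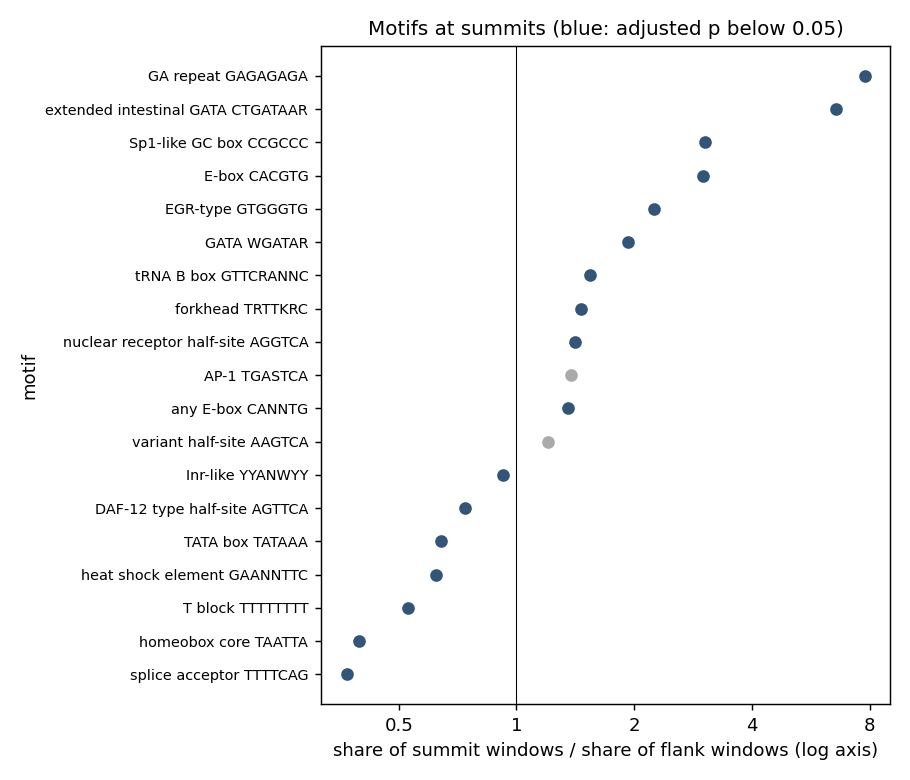
Share of summit windows with a motif divided by the share of flank windows (log axis) for the fixed motifs found in the flanks, blue where the adjusted p is below 0.05. GAGAGAGA (7.77) and CTGATAAR (6.56) lie farthest above 1, and AGGTCA lies at 1.42.

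Last, the loci of the tagged gene and of the strain's unc-119 background were examined. No region of any of the 4 lists lay within 20 kb of nhr-77 (WBGene00003667, chromosome I, 12384277 to 12385731). Near unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the strongest region within 5 kb ranked 7470 in replicate 1, 20159 in replicate 2 and 18808 in the pooled list. None of the thresholded peaks lay there, 0 of 3457.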

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

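The alternatives for chromosome X among the strongest peaks and for the 12-base motif were chosen after the data were seen, and the others before. The share near starts, the excess on X and in the central autosomes, the rank correlation and the counts of classes, motifs and words kept their direction and their side of the threshold, or stayed within 1.5 times, under each alternative run. The replicate overlap was 61.6% and 61.8% with the 1728 strongest regions of each, and 57.6% in both directions with summits within 100 bp. The intergenic share was 27.3% to 27.7% with 1 replicate, above random at the higher value, 36.9% with a window of 250 bp and 19.8% with 1000 bp. The classes compete for the same summits, so a wider start window takes them from the others by construction. Lists higher near peaks numbered 9 against genes with any pooled region, where fewer genes were tested. There the sperm list turned to a log2 odds ratio of 1.43 on 10 members (adjusted exact p = 0.228). The best pooled rank near unc-119 was 6832 within 20 kb, by construction of the wider window. The share on X was 42% in the 50 strongest peaks, 27% in the 100 strongest, 65% in ce10 and 65% to 70% with 1 replicate. Chromosome V was at 19.1% with the 1728 strongest peaks, and with 1 replicate I was at 13.7% to 14.1% and III at 14.4% to 15.2%. Besides the sperm list, single lists lost their call in 13 values and gained it in 2. Single motifs lost it in 8 and gained it in 2, and single gene classes lost it in 1 and gained it in 7. The cause of these was not tested. The extended site TCAAGGTCA had no ratio, since 0 flanks held it. No paired analysis was possible because there was only 1 group. The ce10 lists were not run for the tagged loci, since no annotation of that build was used, and no region near nhr-77 existed to be re-ranked. The share of X peaks among the 100 strongest with the motif was 40.7% with 1 mismatch allowed, 63.0% with 3 (then 17.8% of the autosomal ones, against 2.74%) and 53.8% to 57.1% with 1 replicate. The depth is unknown, so no detection limit can be given for sites outside the lists.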

Other observations

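The tests of the X share by rank, of the share near starts at ranks after 3457 to 20000, of expression in single tissues and of the stretch around nhr-77 were chosen only after the results were seen, and the bound set on the ribosomal proteins among genes with any pooled region was set after that comparison had been run. The 12-base motif and TGATAA by gene list were chosen after the excess on X and the word counts had been seen, but before the values they tested were known.

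Some words at the summits differed in share between the gene lists compared. TGATAA was within 50 bp of 53 of 116 summits near intestinal, lipid, glucuronosyltransferase, cytochrome P450, glutathione transferase and V-ATPase genes (45.7%), and of 1 of 94 summits near ribosomal protein, translation factor and splicing genes (1.06%, two-sided Fisher's exact test, adjusted p = 5.14e-15 over 5 words). CTTATC was at 31.0% and 0 of 94 (adjusted exact p = 8.91e-11). ACGCAG went the other way, with 9.48% and 21.3% (adjusted exact p = 0.0322). GAGAGA (19% and 8.51%, adjusted exact p = 0.0576) and CACGTG (6.03% and 2.13%, adjusted exact p = 0.192) did not pass. Among all summits, TGATAA was at 28.9% and CTTATC at 19.96%. Both contrasts thus came more from near-absence at the translation and splicing genes than from a rise at the first group. That rise was not tested against all summits. A candidate explanation is that the peak set mixes sites bound with or beside intestinal GATA factors and promoter sites of another kind. The value that bears on it is 45.7% against 1.06%, read beside the 28.9% of all summits. Which protein binds these words was not tested.

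The strongest peaks on X may be places where the dosage compensation complex is loaded, since such recruitment elements carry a 12-base motif, taken here from general knowledge as TCGCGCAGGGAG. With at most 2 mismatches it was within 100 bp of 15 of 27 X peaks among the 100 strongest (55.6%) and of 2 of 73 autosomal ones (2.74%, two-sided Fisher's exact test, p = 7.01e-09). It was at 10 of the 13 X peaks of the top 20 and at 1.63% of the weaker X peaks, while 20 shuffled motifs matched at most 2 of the 27. More copies or better recovery of the whole X would raise all ranks. The share on X after rank 500 was 20.3% (Wilson interval 18.9 to 21.8) against 17.7% of the length, so a small effect of this kind stays open. A rise of that size over all ranks does not account for the 65% in the top 20. Whether NHR-77 itself is at these sites, or whether they are recovered with any tagged protein, stays open, since no other tagged strain was analysed here.

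The peaks at broadly expressed genes might reflect non-specific recovery at open or highly expressed genes. High expression in any tissue was examined with 4 lists of single tissues or strong expression. The cuticle collagens, strongly expressed in larval epidermis, were lower, at a log2 odds ratio of -1.58 (95% interval -2.72 to -0.45), as were sperm genes (-1.53). Muscle (0.006) and histones (-0.98) did not pass. Expression was not measured and whole larvae mix all tissues, so these lists cannot decide whether high expression in any tissue raises recovery. Among genes with any pooled region near a start, ribosomal proteins stayed at 4.16 (3.17 to 5.15, 61 of 70). Of the 10000 weakest pooled regions, 21.9% lay near starts against 51.1% of the peaks and 22.9% at random, but the share was 38.6% (Wilson interval 37.4 to 39.7) at ranks after 3457 to 10000 and 25.9% (2586 regions) at the next 10000, which may include weak sites. Recovery of open promoters that falls with rank, or that follows expression, therefore stays open, and no biological explanation was tested.

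Extra copies of a transgene could raise the signal over its own genes. The median pooled signal within 20 kb of unc-119 lay at percentile 12.5 of 1000 random windows, and nhr-77 had no region at all. No rise was thus seen at either gene. This does not exclude extra copies, since how much of either locus the transgene holds was not examined. A control carrying the same copies might instead empty the locus, but the strain and type of the control are not given in the sources used here. The stretch without a pooled region around nhr-77 was 81.6 kb long against a median of 1.47 kb between summits and held 26 whole protein-coding genes, but 18 stretches elsewhere were longer (7 in the list of replicate 1, where it was 69.6 kb, and 24 in that of replicate 2). Of random windows of 41.5 kb, the span searched around nhr-77, 2.91% were also empty. The stretch was thus unusually long but not unique, and its cause cannot be told from these values.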
